A study of Mus musculus with 8 samples.

How the data were processed

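Sciatic nerves of mice aged 30 days were profiled by RNA sequencing, with TruSeq libraries made from poly A selected RNA and read on an Illumina HiSeq2500, per the labels. The mice were F1 animals of C57BL/6 and FVB/N. The 4 genotypes, with 2 libraries each, were wild type (WT), Q215X/+, HA-NRG1 type III/+ with a transgene for the type III form of neuregulin 1, and HA-NRG1 type III/+:Q215X/+, called the double here. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in 3 of the groups. Sex-linked genes read the HA-NRG1 type III/+ libraries as a male and a female, so their spread holds a difference between animals.

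The deposited table holds 1 FPKM value (fragments scaled to gene length and library size) per gene and library for 23356 genes, computed by the authors. TopHat2 2.0.9, Cufflinks 2.2.0 and the mouse build mm10 are listed in the submitters' processing notes. Their roles, the gene annotation, strand handling and any filter are not given in the sources used here. Every line held an empty field after the gene symbol that the header lacks, so the 8 column names were read against the 8 values in order. Columns were joined to genotypes by their name stems. The stem for the transgene is an abbreviation, taken as HA-NRG1 type III/+ because it was the only genotype that no other stem named. Each stem occurred with the endings 0 and 1, called set 0 and set 1 here, and no label ties an ending to a replicate number.

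FPKM values carry no counts, so the depth of a library is unknown and no counting interval is given. Total FPKM per library ran from 443733 to 530901. Common steps between low values, up to 0.05 FPKM, gave relative depths from 0.732 to 1.09, with the WT library of set 0 as 1. That estimate is less firm across sets, where fewer genes shared a step.

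Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, so a log2 difference understates the change of a gene with a low level. The 12530 genes with a mean of at least 1 FPKM over the 8 libraries were tested. A model of 4 group means over all 8 libraries, with 4 residual degrees of freedom and an eBayes trend on the mean, gave 4 comparisons and the interaction (transgene effect in the mutant minus transgene effect in WT). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. An exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333 and was not used for single genes. Values are given as mean ± SD over 2 libraries.

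Before the data were examined, 29 gene lists were fixed from the tissue and genotypes, covering myelin, lipid synthesis, Schwann cell states, stress responses, signalling and the other cell types a nerve sample could hold. Of these, 27 were tested as sets with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists. The list of the targeted genes and the list of sex-linked genes were given as values only. An estimated inter-gene correlation and fry, limma's directional test of a set against no change, were alternatives. The estimated correlation was below the preset one for some lists (−0.0208 for myelin and −0.0646 for red blood cell genes) and above it for others (0.337 for cholesterol genes). A larger p with it is thus not by itself a sign of correlated members. The counts within a list are given over all genes tested and adjusted over the list alone. The latter adjustment does not extend over the lists, comparisons and fits. In HA-NRG1 type III/+ against WT, 2194 of the 12530 genes had an unadjusted limma p under 0.05 with the set as a replicate block. Rises and falls adjusted over a list alone are thus not by themselves a trait of that list. Members found in 1 list can be expressed by several cell types of the nerve.

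The set ending was checked as a pairing before calls were compared. The correlation across genes of the set 1 minus set 0 difference was 0.121 to 0.309 in all 6 pairs of genotypes, and the first principal component separated the sets. The sets were therefore treated as paired, from the data and not from a label. Values of the fit with the set as a replicate block (3 residual degrees of freedom) are given for counts and for part of the single genes whose call they change. Some genes given below as adjusted over a list alone were also called over all genes with the block.

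Named genes were chosen by a rule fixed before the data were examined: a fixed set with Nrg1, Egr2, Jun and Ddit3 always; in each comparison the 8 largest rises and falls among called genes whose groups did not overlap, without predicted genes, short RNA and sex-linked genes; and up to 4 called members of each list, or the 2 members with the smallest p as values. Genes called only with the block, genes named for their response over both backgrounds, Ptpru, Xist, Ddx3y and Mir135a-1 in single comparisons were chosen after their values were seen. Some genes that fell under this rule, and a test that needs one of them, are not reported here. Sex was read from Xist and 4 Y-linked genes, also after values were seen.

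The test steps were run on simulated data with 200 of 12530 genes changed. Each simulated gene had a set difference that was the same in all genotypes, and noise with the spread of the fit with the block. For HA-NRG1 type III/+ against WT, 72.6% of genes changed by 1 log2 unit were recovered without the block and 97.7% with it, and 0.118% and 4.28% of calls were false. For the double against Q215X/+ these values were 72.1% and 98%, and 0.415% and 4.27%. The gain with the block and its share of false calls follow from that construction. They do not show how the block performs where set differences vary between genotypes. Each of the set tests recovered 10 of 10 shifted sets and called 0 unshifted sets for HA-NRG1 type III/+ against WT. The simulated noise was independent between genes and the sets were random genes. This run therefore does not show how often the preset correlation gives false calls for lists with correlated members, such as skeletal muscle (estimated correlation 0.929) or cell cycle genes (0.492).

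Alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, quantile normalization, median ratio rescaling, robust eBayes, an adjusted p under 0.1, only the 4 libraries of a comparison, the replicate block, and each library left out in turn. A term for sex, the block with that term, the removal of short RNA genes, and the block without a single library were added after the values were seen. Only HA-NRG1 type III/+ held both sexes, so the term for sex rests on the difference between its 2 libraries. Without the block that term cannot tell sex from set. Gene coordinates are 1-based on GRCm38.p6, the RefSeq assembly that corresponds to mm10. Of the tested genes, 11699 were found there by symbol, 781 by a synonym and 50 were not found. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. All 8 value columns were used.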

Results

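The 8 libraries were compared as 4 genotypes with 2 libraries each, all from sciatic nerve at an age of 30 days. Total FPKM ran from 443733 to 530901 per library. Genes of microRNA, snoRNA and other short RNA took 1.83% to 10.4% of it. The first principal component held 25.3% of the variance and parted set 0 from set 1 within every genotype, and the second held 20%.

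Nrg1, which encodes the ligand neuregulin 1 for ERBB receptors, was below the level for testing in every group, at 0.184 ± 0.0285 FPKM in WT (SD, n = 2), 0.258 ± 0.0965 in Q215X/+, 0.352 ± 0.0575 in HA-NRG1 type III/+ and 0.428 ± 0.0993 in the double. Its mean FPKM ratio was 1.92 for HA-NRG1 type III/+ to WT and 1.66 for the double to Q215X/+, with Benjamini-Hochberg adjusted p = 0.63 and 0.659 in limma without a filter. Nrg1 lies on chromosome 8 at 31807452 to 32891609, and whether the table counts transgene reads under it is not given in the sources used here.

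The sexes of the libraries, read from Xist (the RNA of the inactive X) and the Y-linked Ddx3y, followed genotype in part. Xist was at 70.5 and 76.3 FPKM in WT, 0.139 and 0.0644 in Q215X/+, 58.3 and 73.8 in the double, and 0.0428 and 73.6 in sets 0 and 1 of HA-NRG1 type III/+. Ddx3y was at 26.4 and 24.4 FPKM in Q215X/+ and 27.6 in set 0 of HA-NRG1 type III/+, and under 0.05 in the other libraries. Both WT and both double libraries thus read as female, both Q215X/+ libraries as male, and HA-NRG1 type III/+ as 1 of each. Sex is therefore confounded with genotype in Q215X/+ against WT and in the double against Q215X/+. It enters HA-NRG1 type III/+ against WT in part, through the male library of set 0. Sex runs in opposite directions in the transgene comparisons on the WT and mutant backgrounds, so it enters the interaction as well.

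**Figure D1:**
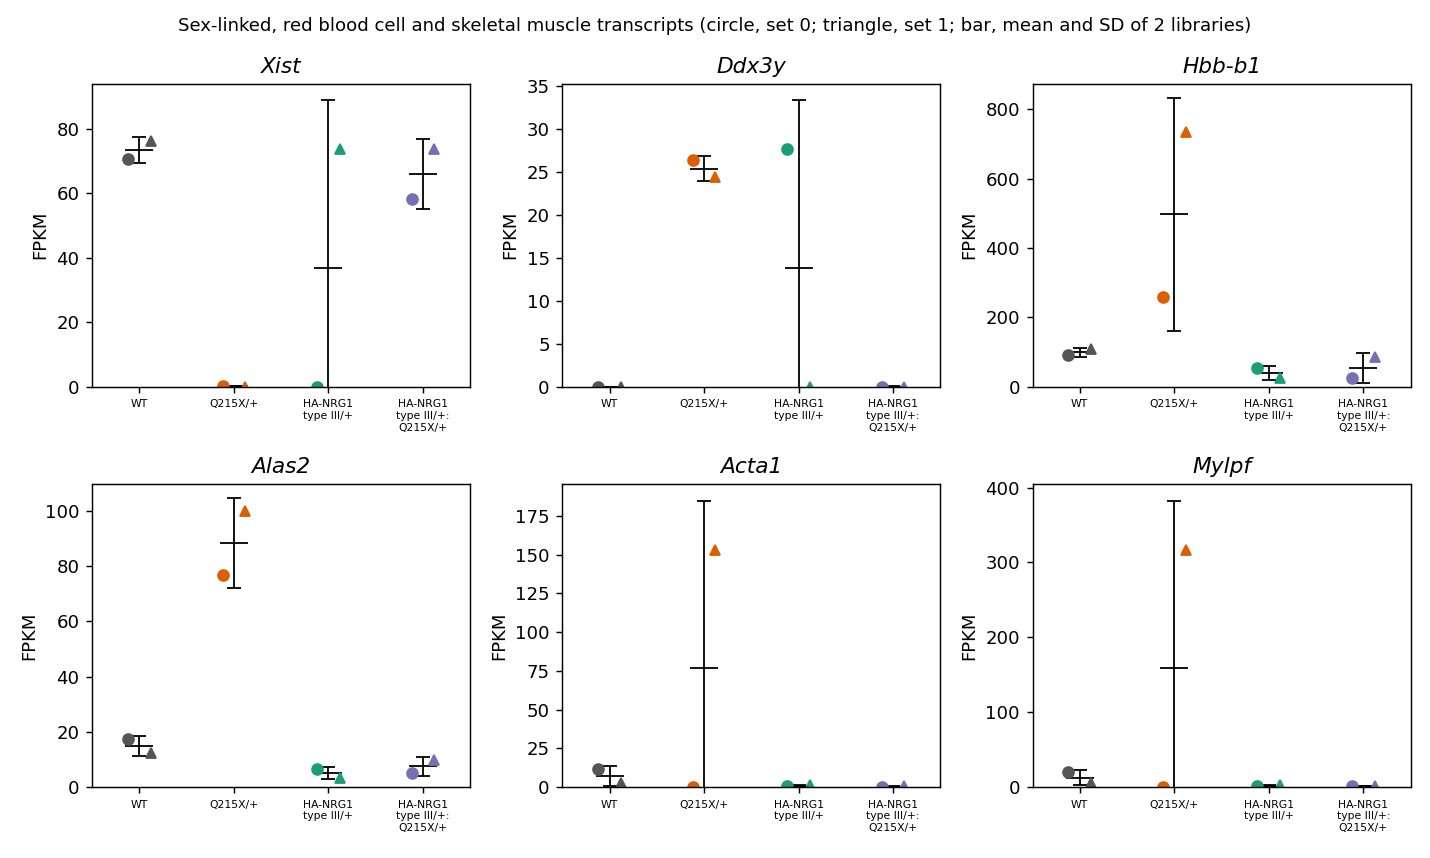
FPKM per library of the sex-linked Xist and Ddx3y, the blood genes Hbb-b1 and Alas2 and the muscle genes Acta1 and Mylpf by genotype, with circles for set 0, triangles for set 1 and bars for mean ± SD of 2 libraries (lower ends stop at 0). Acta1 reached 153 FPKM in a single Q215X/+ library, and Alas2 was higher in both Q215X/+ libraries than in the other 6.

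The comparison of Q215X/+ with WT asks what the Q215X mutation changes on a wild-type background. The lists of cholesterol synthesis and uptake and of endothelial genes lay below other genes in Q215X/+, and those of red blood cell and cell cycle genes lay above. Of 24 measured cholesterol genes, 23 were below 0, with a median of −0.20 log2 units (camera adjusted p = 2.91e-09, and adjusted p = 0.51 with an estimated correlation). Of 18 endothelial genes, 17 were below 0, with a median of −0.22 (adjusted p = 2.91e-09, and 0.49 with an estimated correlation). Of the 22 cell cycle genes, 19 were above 0, with a median of 0.25 (adjusted p = 1.74e-08, and 0.595 with an estimated correlation). Red blood cell genes had a median of 2.07 (adjusted p = 1.15e-07, and 0.122 with an estimated correlation).

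Of the cholesterol genes, limma called 0 over all genes and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05. Sc5d, a desaturase of cholesterol synthesis, had a log2 difference of −0.26 (SE 0.10). In the endothelial list Slco1a4, an organic anion transporter of vessel walls, fell by 0.37 (SE 0.08) when adjusted over the list alone, from 10.1 ± 0.273 to 7.63 ± 0.241 FPKM (SD, n = 2), and with the block the junction gene Cldn5 and the receptor gene Eng fell in the same way. Of the red blood cell genes, 3 of 5 rose when adjusted over the list alone: Alas2, the erythroid enzyme of haem synthesis, Hbb-b1 and Hbb-b2. Alas2 stood at 88.4 ± 16.3 FPKM in Q215X/+ and 15.0 ± 3.67 in WT. Hbb-b1 stood at 497 ± 336 and 99.0 ± 12.2, and the globin genes are close copies whose reads may be split between them. Among cell cycle genes, limma called 0 over all genes and 0 when adjusted over the list alone, with 3 at an unadjusted p under 0.05. Nusap1, which bundles spindle microtubules, had a log2 difference of 0.51 (SE 0.14) and Cdc20, an activator of mitotic exit, 0.43 (SE 0.13).

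Further lists passed at the preset correlation. Fatty acid and sphingolipid synthesis (median −0.10, camera adjusted p = 0.0013, and 0.595 with an estimated correlation) and pericyte and smooth muscle genes (median −0.10, adjusted p = 0.0014, and 0.49 with an estimated correlation) lay lower. Myelination transcription factors had a median of −0.06 (adjusted p = 0.0403, 0.754 with an estimated correlation, and 0.0584 with the block), and its member Hmga1, a chromatin protein, fell by 0.65 (SE 0.09) when adjusted over the list alone. Egr2, the master factor of peripheral myelination, stood at 69.7 and 53.2 FPKM in Q215X/+ and 71.9 and 49.3 in WT. Nuclear-encoded respiratory chain genes had a median of 0.09 (adjusted p = 0.0237, and 0.835 with an estimated correlation). Skeletal muscle genes had a median of 1.02 (adjusted p = 0.000968, and 0.754 with an estimated correlation), which rests on the set 1 library of Q215X/+: Mylpf was at 317 FPKM there and at 0.668 in set 0. With the block, cytosolic ribosomal protein genes, with a median of −0.09, also passed (adjusted p = 0.0026, and 0.726 with an estimated correlation). The myelin list had a median of −0.05 (adjusted p = 0.573) and the unfolded protein response list a median of 0.02 (adjusted p = 0.612). The 18 lists that did not pass had adjusted p from 0.179 to 0.93. With the block and adjusted over each list alone, 1 myelin gene rose, 1 gene fell in each of the cholesterol, macrophage and both Schwann cell lists, and of the immediate early genes 1 rose and 2 fell. Ddit3, a stress-induced transcription factor, stood at 20.4 and 22.8 FPKM against 21.2 and 24.9 in WT, and Jun, the factor that drives the repair state of Schwann cells, at 19.6 ± 1.72 against 17.2 ± 2.25.

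Over all genes, limma called 1 rise and 0 falls between Q215X/+ and WT, and 255 genes had an unadjusted p under 0.05 (929 with the block, which also called 1, and 1 to 20 without any one library). The gene was Mir135a-1 on chromosome 9 at 106154124 to 106154213, at 148 and 185 FPKM in Q215X/+ and listed at 0 in the other 6 libraries. It is a short microRNA gene, overlaps Glyctk (0.608 to 0.892 FPKM over the libraries), and without short RNA genes the count was 0. The count was 10 without either WT library, 7 without either HA-NRG1 type III/+ library, 15 without the Q215X/+ library of set 0 and 6 without that of set 1, and 8 with a term for sex and 9 with that term and the block.

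**Figure D2:**
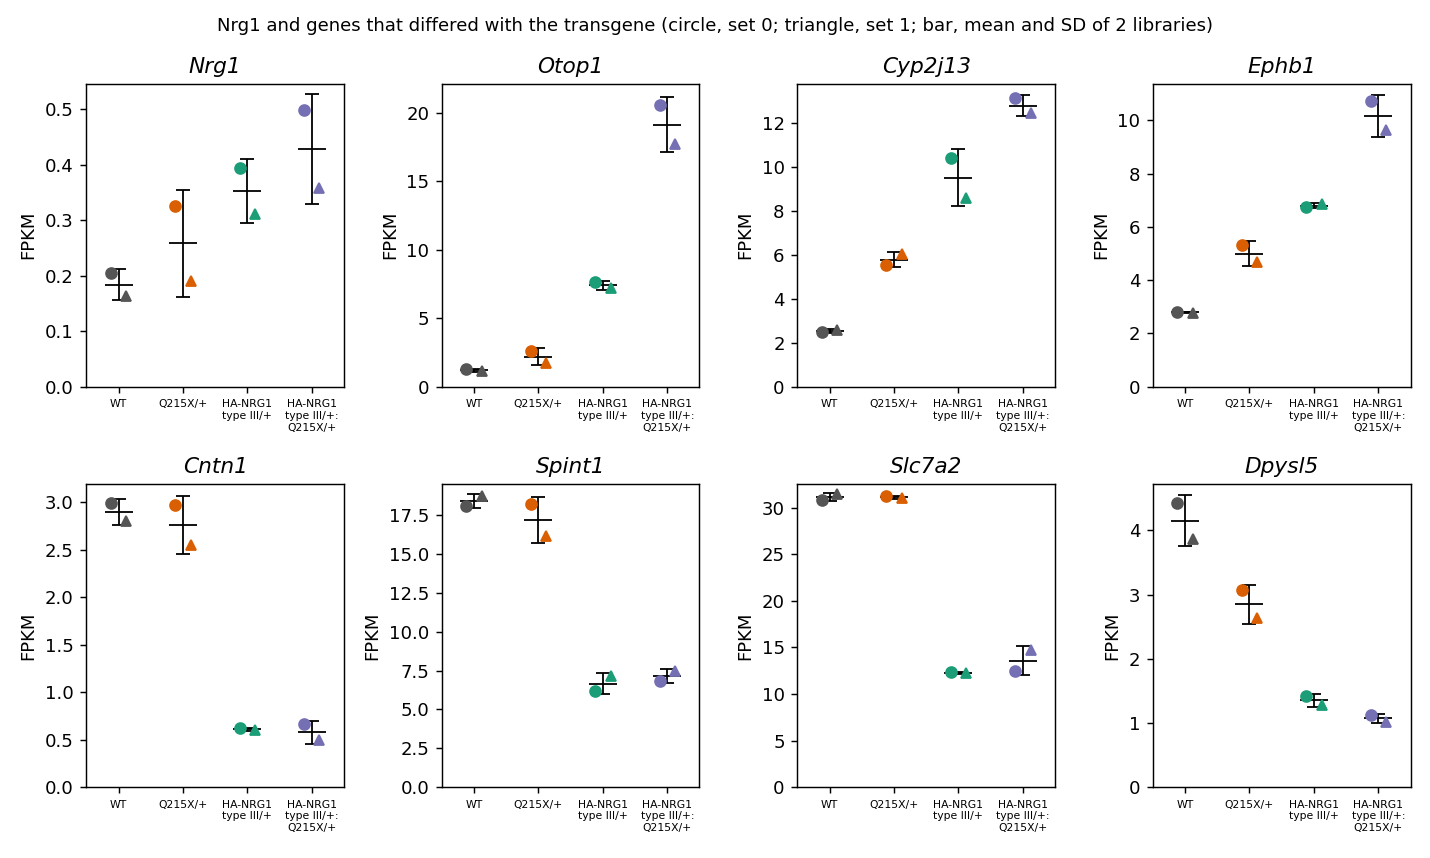
FPKM of 8 genes in each library by genotype, with circles for set 0, triangles for set 1 and bars for mean ± SD of 2 libraries. Otop1, Cyp2j13 and Ephb1 were higher and Cntn1, Spint1, Slc7a2 and Dpysl5 lower in all 4 libraries with the transgene than in the 4 without it.

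The comparison of HA-NRG1 type III/+ with WT asks what the transgene changes in a nerve without the mutation. Otop1, which encodes a proton channel, rose from 1.19 ± 0.0991 to 7.41 ± 0.339 FPKM (SD, n = 2), a log2 difference of 1.94 (SE 0.15, limma with Benjamini-Hochberg adjusted p = 0.0218). Cyp2j13, a cytochrome P450 gene with close paralogs in a cluster that may share reads, rose by 1.57 (SE 0.10, adjusted p = 0.0218). Ephb1, a receptor tyrosine kinase for ephrin-B ligands, rose from 2.80 ± 0.0172 to 6.80 ± 0.0980 FPKM (adjusted p = 0.0299), and Ly9, a receptor of the SLAM family on lymphocytes, rose by 0.91 (SE 0.07, adjusted p = 0.0218). Spint1, an inhibitor of serine proteases, fell by 1.34 (SE 0.10, adjusted p = 0.0218), Cntn1, the axonal and paranodal adhesion protein contactin, fell by 1.27 (SE 0.11, adjusted p = 0.0299), Slc7a2, a transporter of cationic amino acids, fell by 1.27 (SE 0.09, adjusted p = 0.0218) and Dpysl5, a protein of growing axons, fell by 1.13 (SE 0.11, adjusted p = 0.0456).

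These 4 rises and 4 falls were all the calls, with 865 genes at an unadjusted p under 0.05. Otop1 lies on chromosome 5 at 38277404 to 38304217, Ephb1 on chromosome 9 at 101922128 to 102354693, Cntn1 on chromosome 15 at 92051152 to 92341967, Spint1 on chromosome 2 at 119237360 to 119249535 and Slc7a2 on chromosome 8 at 40862341 to 40922070. Ly9 lies on chromosome 1 at 171588613 to 171607410 and Cyp2j13 on chromosome 4 at 96042660 to 96077566. Dpysl5 lies on the chromosome of Otop1, at 30711564 to 30799369. With the block, 132 genes rose and 133 fell, and these 265 became 14 and 11 without the WT libraries of sets 0 and 1, 11 and 19 without those of HA-NRG1 type III/+, 4 without either double library and 11 with a term for sex. The count of 8 became 5 without the HA-NRG1 type III/+ library of set 0 (a male), 2 without either Q215X/+ library and 1 without either double library, and 0 without a filter. A term for sex gave 6 rises and 0 falls and ended all of the 8 calls but Cyp2j13 (adjusted p = 0.122 to 0.186), with Slc7a2 at −1.27 (SE 0.0917) before and −1.28 (SE 0.125) after. With the term for sex the log2 differences were those without the HA-NRG1 type III/+ library of set 0 (Otop1 1.90, Cyp2j13 1.44), so these 2 fits are not separate checks. With that term and the block, Ephb1, Ly9, Spint1, Cntn1 and Dpysl5 were not called either (adjusted p = 0.0674 to 0.0817). The calls of Ephb1, Ly9, Spint1, Cntn1, Slc7a2 and Dpysl5 ended without any one of the 8 libraries. That of Otop1 ended without any one WT, HA-NRG1 type III/+ or double library, and that of Cyp2j13 without any one library but the HA-NRG1 type III/+ library of set 1. Without a Q215X/+ or double library the log2 differences did not change (Ephb1 1.04, Slc7a2 −1.27). There the calls ended through the estimate of the spread, with fewer residual degrees of freedom, and not through the size of the difference.

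The myelin list lay below other genes in HA-NRG1 type III/+, with 23 of 29 members below 0 and a median of −0.17 (camera adjusted p = 0.0053, adjusted p = 0.36 with an estimated correlation, fry adjusted p = 0.015). Cnp, the cyclic nucleotide phosphodiesterase of myelinating cells, went from 903 ± 84.2 to 487 ± 49.0 FPKM (SD, n = 2) and fell when adjusted over the list alone, while Pmp2, the fatty acid binding protein of peripheral myelin, went from 1010 ± 73.7 to 2493 ± 533 FPKM and rose when adjusted over the list alone. Over all genes limma called neither (adjusted p = 0.197 for both), and with the block it called both (adjusted p = 0.00842 for Cnp and 0.0192 for Pmp2), together with falls of the membrane protein Pllp (log2 −0.47, adjusted p = 0.035) and the sphingolipid hydroxylase Fa2h (−0.39, adjusted p = 0.0494). With the block and adjusted over the list alone, 2 myelin genes rose and 8 fell.

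Macrophage genes lay above other genes, with 21 of 26 above 0 and a median of 0.21 (camera adjusted p = 0.00127, and 0.808 with an estimated correlation). Adjusted over the list alone, Trem2, a receptor of lipid-laden macrophages, and Mpeg1, a pore-forming protein, rose, and the scavenger receptor Cd163 fell. Over all genes limma called 0, with 6 at an unadjusted p under 0.05. With the block, Cx3cr1, Ms4a7 and the protease gene Ctss rose by 0.64 (adjusted p = 0.0435), 0.75 (0.0175) and 0.51 (0.0451), and adjusted over the list alone 6 rose and 1 fell. Axonal genes had a median of −0.41 (camera adjusted p = 0.00764, and 0.808 with an estimated correlation), and the intermediate filament genes Nefh, Nefm and Prph fell when adjusted over the list alone, with Nefh at 5.36 ± 1.46 FPKM in WT and 1.78 ± 0.332 in HA-NRG1 type III/+ (SD, n = 2). Fibroblast genes had a median of 0.19 (adjusted p = 0.0387, and 0.436 with an estimated correlation), and with the block the matrix genes Thbs2 (log2 0.64, adjusted p = 0.0175) and Lum (0.54, adjusted p = 0.0304) rose. Cell cycle genes had a median of 0.29 (adjusted p = 0.000134, and 0.808 with an estimated correlation), and the list of lymphocytes and mast cells a median of 0.59 (adjusted p = 0.0387, 0.887 with an estimated correlation, and 0.0961 with the block).

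Red blood cell genes were lower in HA-NRG1 type III/+, with 5 of 5 below 0, a median of −1.41 (camera adjusted p = 0.0053, and 0.36 with an estimated correlation) and Hbb-b1 at 39.0 ± 20.2 FPKM. With the block cytosolic ribosomal protein genes, with a median of −0.09, passed as well (adjusted p = 0.0246, and 0.996 with an estimated correlation). Erbb4, a receptor for neuregulins, rose with the block (log2 0.62, adjusted p = 0.0172), and Erbb2 and Erbb3, the receptor pair of Schwann cells, had log2 differences of −0.27 (SE 0.11) and −0.35 (SE 0.15), with adjusted p = 0.71 and 0.741. Adjusted over the list alone, Ucn2 of the immature and repair Schwann cell list and Adamtsl1 of the non-myelinating Schwann cell list rose, and Scn7a and Cdh2 of the latter fell. Ucn2, a peptide of the corticotropin-releasing family, had a log2 difference of 1.30 (SE 0.25) and Adamtsl1, a matrix protein, 1.02 (SE 0.13). Neither list passed as a set (camera adjusted p = 0.671 and 0.861). Dusp4, a phosphatase that limits ERK signalling, went from 4.63 ± 0.176 to 9.64 ± 1.57 FPKM (SD, n = 2) and rose when adjusted over its list of ERK targets alone, with a log2 difference of 0.91 (SE 0.185), while the list did not pass (camera adjusted p = 0.414). A term for sex beside the block, in a fit with 1 residual degree of freedom less, ended the calls of Cnp, Pmp2, Pllp, Fa2h, Cx3cr1, Ms4a7, Ctss, Thbs2, Lum and Erbb4 (adjusted p = 0.0864 to 0.289). The SE widened for Cnp, at −0.89 (SE 0.0641) before and −0.86 (SE 0.0991) after, but not for Cx3cr1, at 0.64 (SE 0.102) and 0.81 (SE 0.0813). In the double against WT the same fit still called Cnp, Pmp2, Cx3cr1, Ms4a7, Ctss, Thbs2 and Erbb4 (adjusted p = 0.0186 to 0.0408), but not Pllp, Lum and Fa2h (0.0621 to 0.0732). Asns, which makes asparagine, rose and the collagen Col28a1 fell when adjusted over their lists of amino acid stress genes and of basement membrane genes alone. With the block and adjusted over each list alone, rises and falls were 5 and 4 for immature and repair Schwann cell, 2 and 4 for non-myelinating Schwann cell, 2 and 4 for fatty acid and sphingolipid, 1 and 4 for amino acid stress, 3 and 2 for basement membrane and 1 and 6 for axonal genes. They were 6 and 0 for fibroblast, 1 and 2 for ERK target, 2 and 1 for ERBB receptor, 0 and 2 for myelination factor, and 1 and 1 for unfolded protein response and for endothelial genes. The 20 lists that did not pass had adjusted p from 0.126 to 0.985. The number of lists past the threshold was 7, and 4 without the HA-NRG1 type III/+ library of set 1.

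The comparison of the double with Q215X/+ asks what the transgene changes in the mutant nerve, the question that the series title names. Otop1 rose from 2.2 ± 0.622 to 19.1 ± 1.98 FPKM (SD, n = 2), a log2 difference of 2.66 (SE 0.15, limma with Benjamini-Hochberg adjusted p = 0.00605). Cntn1 fell by 1.25 (SE 0.11, adjusted p = 0.0446), Spint1 fell by 1.16 (SE 0.10, adjusted p = 0.0446) and Slc7a2 fell by 1.14 (SE 0.09, adjusted p = 0.0414). Mir135a-1 went from 167 ± 26.3 FPKM to a listed value of 0 (adjusted p = 4.83e-06). Cyp2j13, Ephb1 and Ly9 had log2 differences of 1.02, 0.90 and 0.70, with adjusted p = 0.0595 for each, and rose with the block (adjusted p = 0.0155, 0.0129 and 0.0131).

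These 5 genes were all the calls, with 825 at an unadjusted p under 0.05. With the block, 107 genes rose and 109 fell. The count of 5 became 1 without either WT library, 17 without the Q215X/+ library of set 0 and 8 without that of set 1, 3 without a filter, 14 without short RNA genes and 9 with a term for sex. That term ended the calls of Otop1 (adjusted p = 0.122), Cntn1 (0.829), Spint1 (0.32) and Slc7a2 (0.699), with Cntn1 at −1.25 (SE 0.111) before and −1.23 (SE 0.203) after, and with the block as well Cntn1, Spint1 and Slc7a2 were at 0.284, 0.257 and 0.345. The adjusted p of Cntn1, Spint1 and Slc7a2 was 0.0545 to 0.357 without any one of the 8 libraries. That of Otop1 was 0.0544 and 0.0548 without the WT libraries of sets 0 and 1. The 216 with the block became 17 and 19 without the WT libraries of sets 0 and 1, 73 and 25 without those of Q215X/+, 51 without either HA-NRG1 type III/+ library, 5 and 6 without the double libraries and 11 with a term for sex. A term for sex beside the block also ended the calls of Cyp2j13, Ephb1, Ly9, Cnp and Alas2 (adjusted p = 0.173 to 0.66), with Ephb1 at 0.90 (SE 0.0729) before and 0.77 (SE 0.136) after.

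Myelin genes again lay lower, with 24 of 29 below 0 and a median of −0.15 (camera adjusted p = 0.000132, adjusted p = 0.121 with an estimated correlation, fry adjusted p = 0.00421). Cnp stood at 479 ± 34.6 FPKM against 858 ± 54.8 in Q215X/+ (SD, n = 2) and fell when adjusted over the list alone and, with the block, over all genes (adjusted p = 0.012). With the block and adjusted over the list alone, 1 myelin gene rose and 10 fell. Macrophage genes lay higher, with 25 of 26 above 0 and a median of 0.23 (adjusted p = 2.42e-06, and 0.366 with an estimated correlation). Trem2, Mpeg1 and Ctss rose and Cd163 fell when adjusted over the list alone, and Trem2 went from 6.72 ± 0.912 to 10.7 ± 0.128 FPKM. Targets of the ERK pathway lay higher, with 17 of 18 above 0 and a median of 0.16 (adjusted p = 0.000319, and 0.366 with an estimated correlation). Dusp4 rose when adjusted over the list alone, with a log2 difference of 0.88 (SE 0.185), and with the block 7 of the 18 rose in this way.

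Perineurial genes were above 0 in 11 of 11 cases, with a median of 0.23 (camera adjusted p = 4.47e-05, and 0.366 with an estimated correlation). The connexin gene Gjb2 and Msln rose when adjusted over the list alone, from 3.88 ± 0.420 to 9.21 ± 0.201 FPKM for Gjb2 (SD, n = 2). Endothelial genes were above 0 in 17 of 18 cases, with a median of 0.22 (adjusted p = 0.000132, and 0.428 with an estimated correlation), and axonal genes had a median of −0.31 (adjusted p = 0.023, and 0.572 with an estimated correlation), with 6 falls, Nefl, Nefm, Nefh and Prph among them, and 1 rise, of Uchl1, when adjusted over the list alone with the block. Cholesterol genes had a median of −0.12 (adjusted p = 0.0165, and 0.631 with an estimated correlation) and heat shock genes −0.14 (adjusted p = 0.0488, and 0.374 with an estimated correlation). Lymphocyte and mast cell genes had a median of 0.45 (adjusted p = 0.0336, 0.572 with an estimated correlation, and 0.0837 with the block). Respiratory chain genes, with a median of −0.09, passed with the block only (adjusted p = 0.00141, and 0.685 with an estimated correlation). Outside these lists, Ucn2 (log2 1.68, SE 0.25), Adamtsl1 (0.71, SE 0.13), Asns (0.53, SE 0.09), Hmga1 (0.58, SE 0.09) and the matrix genes Thbs2 (0.79, SE 0.18) and Lum (0.57, SE 0.13) rose when adjusted over their lists alone. With the block, such rises and falls were 3 and 2 for immature and repair Schwann cell, 2 and 4 for non-myelinating Schwann cell, 4 and 4 for fatty acid and sphingolipid, 1 and 3 for amino acid stress, 2 and 2 for basement membrane and 7 and 1 for macrophage genes. They were 2 and 0 for endothelial, 1 and 0 for pericyte and smooth muscle, 1 and 1 for ERBB receptor and for immediate early, and 0 and 0 for lymphocyte and mast cell genes (1 and 0 without the block). The 16 lists that did not pass had adjusted p from 0.0758 to 0.995.

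Blood and muscle transcripts differed in the same comparison. Red blood cell genes had a median of −2.47 (camera adjusted p = 6.2e-08, adjusted p = 0.0988 with an estimated correlation, fry adjusted p = 0.00687), and 4 of 5 fell when adjusted over the list alone. Alas2 went from 88.4 ± 16.3 to 7.58 ± 3.37 FPKM (SD, n = 2, adjusted p = 0.0595 without the block and 0.0264 with it). Skeletal muscle genes had a median of −2.42 (adjusted p = 4.47e-05, and 0.572 with an estimated correlation), again through the single Q215X/+ library in which Mylpf reached 317 FPKM.

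**Figure D3:**
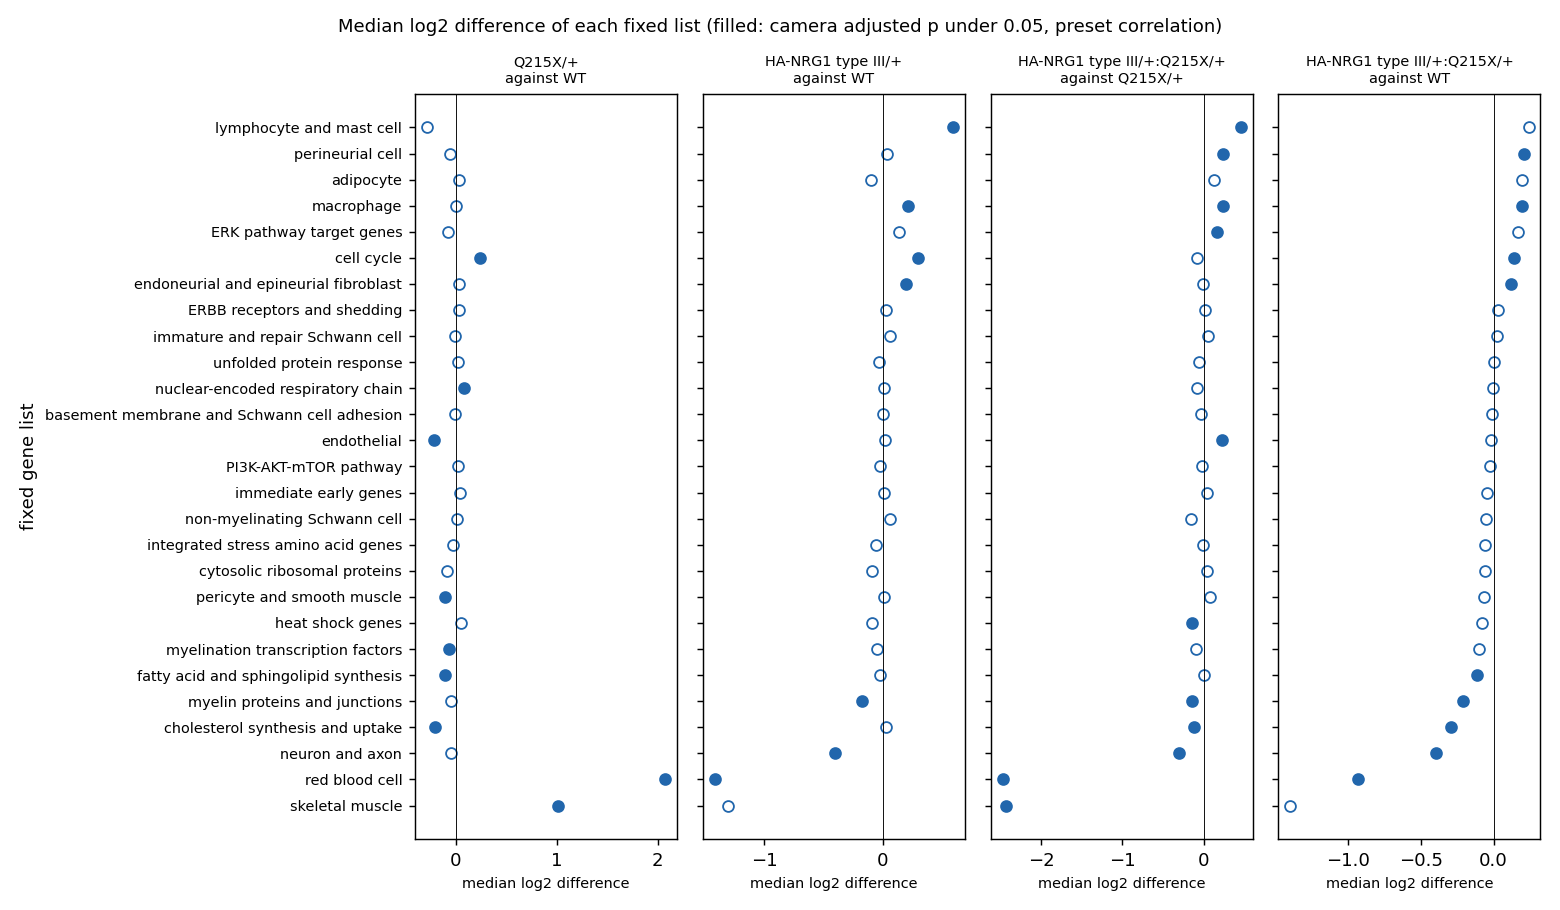
Median log2 difference of each fixed list in the 4 comparisons, 1 panel each with its own horizontal scale, with filled points for lists at a camera adjusted p under 0.05 at the preset correlation. The myelin list was below 0 and filled in the 3 comparisons that involve the transgene, and the cholesterol list was filled below 0 in Q215X/+ against WT and in both comparisons of the double.

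The comparison of the double with WT asks what differs from a normal nerve when both alleles are present, and both groups read as female. Otop1 rose from 1.19 ± 0.0991 to 19.1 ± 1.98 FPKM (SD, n = 2), a log2 difference of 3.20 (SE 0.15, limma with Benjamini-Hochberg adjusted p = 0.00384). Lect1, the cartilage factor chondromodulin, rose from 15.3 ± 0.801 to 90.6 ± 0.517 FPKM (adjusted p = 0.0157), Ephb1 from 2.80 ± 0.0172 to 10.2 ± 0.790 (adjusted p = 0.00563) and Emid1, a secreted protein with an EMI domain, from 116 ± 5.79 to 272 ± 2.26 (adjusted p = 0.0199). Cyp2j13 rose by 1.96, Fgl2, a fibrinogen-like protein, by 1.42, Leprel1, a collagen prolyl hydroxylase, by 1.36, Vtcn1, an inhibitory ligand of T cells, by 1.26 (adjusted p = 0.046) and the receptor phosphatase Ptpru by 1.04. Dpysl5, Cntn1, Spint1 and Slc7a2 fell by 1.31, 1.31, 1.25 and 1.14, with adjusted p = 0.0157 each, and Nr2f1, a nuclear receptor of neural development, fell by 1.07 (adjusted p = 0.0199).

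Of all genes, 9 rose and 5 fell, with 913 at an unadjusted p under 0.05, and with the block 144 rose and 155 fell. The count of 14 became 8 without the Q215X/+ library of set 1, 4 and 7 without the double libraries of sets 0 and 1, and 4 with only the 4 libraries compared. Otop1 passed without any one library, while without the double library of set 0 the adjusted p was 0.0514 for Cyp2j13 and 0.0552 for Ephb1. For Lect1, Fgl2, Leprel1, Vtcn1, Emid1, Dpysl5, Cntn1 and Spint1 it was 0.0631 to 0.359 without any one of the 4 libraries compared. For Slc7a2 it was 0.0995 to 0.131 without either WT library or the double library of set 0, and for Nr2f1 0.0814 to 0.24 without any one library but the WT library of set 0. Without either Q215X/+ library it was 0.0612 to 0.129 for Vtcn1, Emid1 and Slc7a2, and without that of set 1 it was 0.051 for Fgl2. With a term for sex it was 0.0799 for Nr2f1. The 299 calls with the block became 24 and 21 without the WT libraries of sets 0 and 1, 95 without either HA-NRG1 type III/+ library, 9 and 8 without the double libraries and 98 with a term for sex.

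Cholesterol genes were below 0 in 24 of 24 cases, with a median of −0.29 (camera adjusted p = 2.39e-10, and 0.421 with an estimated correlation). Over all genes limma called 0 of them, with 8 at an unadjusted p under 0.05, and with the block it called falls of Insig1, the sterol sensor (log2 −0.52, adjusted p = 0.0341) and Idi1, an isomerase of the pathway (−0.39, adjusted p = 0.0495, and 0.0854 with a term for sex as well). With the block and adjusted over the list alone, 16 of the 24 fell. Fatty acid and sphingolipid genes had a median of −0.12 (adjusted p = 0.0478, 0.751 with an estimated correlation, and 0.0636 with the block). Myelin genes were below 0 in 25 of 29 cases, with a median of −0.21 (adjusted p = 9.49e-05, adjusted p = 0.204 with an estimated correlation, fry adjusted p = 0.0016). Adjusted over the list alone, Pmp2 rose and Cnp, Mpdz, Fa2h and Sh3tc2 fell, and with the block 2 rose and 15 fell in this way. Over all genes the block called 1 rise and 6 falls in the list, among them Cnp (adjusted p = 0.0047), Pmp2 (0.0229), Mpdz and Fa2h (0.0295 each) and Sh3tc2 (0.047). With a term for sex as well, Cnp and Pmp2 passed (0.0287 and 0.0388), but not Mpdz, Fa2h and Sh3tc2 (0.0656 to 0.0886).

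Macrophage genes had a median of 0.20 (camera adjusted p = 1.54e-05, and 0.489 with an estimated correlation), with 4 rises adjusted over the list alone and Cx3cr1, Ms4a7, Ctss and Trem2 called with the block (Trem2 not with a term for sex as well, adjusted p = 0.0749). Perineurial genes had a median of 0.21 (adjusted p = 0.00221, and 0.489 with an estimated correlation), fibroblast genes 0.12 (adjusted p = 0.0243, and 0.421 with an estimated correlation) and cell cycle genes 0.14 (adjusted p = 0.0237, and 0.832 with an estimated correlation). Axonal genes had a median of −0.40 (adjusted p = 0.0312, 0.751 with an estimated correlation, and 0.0636 with the block) and red blood cell genes −0.93 (adjusted p = 0.0256, 0.421 with an estimated correlation, and 0.118 with the block). Targets of the ERK pathway, with a median of 0.17, passed with the block only (adjusted p = 0.0259, and 0.75 with an estimated correlation). Endothelial genes had a median of −0.02 (adjusted p = 0.701). Adjusted over their lists alone, Ucn2 (log2 1.91, SE 0.25), Adamtsl1 (0.90, SE 0.13), Dusp4 (1.09, SE 0.185) and Egr1 (0.78, SE 0.18), an early gene of growth factor signalling, rose. With the block, such rises and falls were 2 and 4 for immature and repair Schwann cell, 1 and 4 for non-myelinating Schwann cell, 3 and 8 for fatty acid and sphingolipid, 1 and 2 for amino acid stress, 3 and 2 for basement membrane, 2 and 6 for axonal and 6 and 0 for macrophage genes. They were 4 and 0 for fibroblast, 4 and 1 for ERK target, 2 and 1 for ERBB receptor, 1 and 2 for myelination factor, 1 and 0 for immediate early and for PI3K pathway, and 0 and 1 for endothelial genes. The 18 lists that did not pass had adjusted p from 0.0745 to 0.987.

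The interaction asks whether the transgene acts differently in the mutant, and it also takes in sex. It called 1 gene, Mir135a-1, and 139 genes had an unadjusted p under 0.05 (599 with the block, with the same count of 1, and 3 to 12 without any one library). The count was 3 to 11 without any one of the 8 libraries, 9 with a term for sex and 0 without short RNA genes. Across genes, the transgene effect on the WT background correlated with that on the mutant background with Pearson r = 0.218 and Spearman rho = 0.48, and with r = 0.599 and rho = 0.489 without sex-linked and short RNA genes. Genes are not independent replicates, and the compared differences share 0 libraries. The transgene r was 0.094 without the HA-NRG1 type III/+ library of set 1 and 0.132 without the double library of set 0. The same correlation for the mutation effect was r = 0.0192 and rho = 0.0461 (0.0855 and 0.0492 without sex-linked and short RNA genes), with r = −0.105 and 0.122 without the HA-NRG1 type III/+ libraries of sets 1 and 0. Sex runs in opposite directions in the compared differences, for the transgene and for the mutation, so genes that follow sex lower both correlations. With the block, 60 genes rose in both transgene comparisons, against 1.13 for independent lists, and 68 fell in both, against 1.16, with 0 in opposite directions. Both comparisons use the same estimate of each gene's spread, so the lists are not independent and these references tend to be too low. Without the block Otop1 rose and Cntn1, Spint1 and Slc7a2 fell in both. Without any one library 1 to 26 genes were called in both with the same direction, and 1 with a term for sex. In each of these fits all 128 kept their directions, which their choice from the same libraries favours, so that calls were lost and not directions. Without the HA-NRG1 type III/+ library of set 1, and with the term for sex, 5 called genes went in opposite directions, all of them sex-linked or short RNA genes. Of the 265 genes called on the WT background with the block, 257 (97.0%) had the same sign in the mutant. Without the Q215X/+ libraries of sets 0 and 1 this held for 90.7% of 204 and 96.4% of 221, without those of WT for 28.6% of 14 and 27.3% of 11, without those of HA-NRG1 type III/+ for 54.5% of 11 and 63.2% of 19, without those of the double for 75% and 100% of 4, and with the term for sex for 45.5% of 11.

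**Figure D4:**
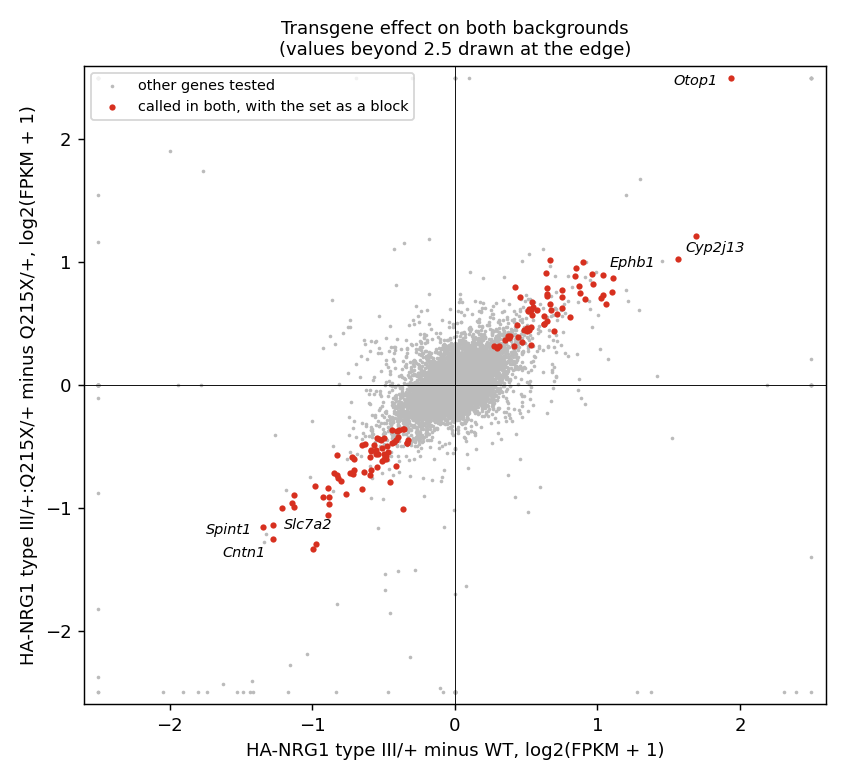
Log2 difference of each gene for HA-NRG1 type III/+ against WT (horizontal) and for the double against Q215X/+ (vertical), with the 128 genes called in both with the block in red and values beyond the axes drawn at the edge. The red points lie at the lower left and upper right, and 0 of them had opposite signs.

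Genes called for the mutation were asked for their shift with the transgene. The only such gene was Mir135a-1, with a shift of −7.38 on the log2(FPKM + 1) scale, where 50 simulated data sets without a transgene effect had a median of −0.0994 and a lowest value of −3.96. Those sets called a median of 6 genes each and give medians over them, so the value of this single gene, listed at 0 in 6 libraries, cannot be ranked among them. For 200 genes chosen on 1 set and measured in the other, the mutation effect kept −0.0432 of a log2 unit on average in its own direction and the shift was 0.0714. The genes chosen in this way thus did not hold their mutation effect in the other set, so the shift of mutation effects could not be read from them.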

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

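The tests of common steps between low values, of sex, of erythroid genes below the expression filter and of splits with the block were chosen after the result was seen.

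Mir135a-1 was the gene for which the transgene effect in the mutant differed from that in WT by a test of the difference itself. The interaction was −7.38 on the log2(FPKM + 1) scale (limma with Benjamini-Hochberg adjusted p = 4.43e-05), and its size depends on the pseudocount, because the gene was listed at 0 in the 6 libraries that were not Q215X/+. The Q215X/+ libraries listed 148 and 185 FPKM. The gene is short, overlaps Glyctk, whose FPKM was 0.608 to 0.892 over the 8 libraries, and no technical or biological explanation was tested for it.

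With the set as a block, the calls in the 3 comparisons that involve the transgene summed to 780, and without any one library the 3 counts were 4 to 221, 5 to 73 and 8 to 241. The other 7 ways to pair the libraries across genotypes gave at most 13, which argues against pairing as such as the reason. Pairs of libraries of the same set shared a common step between low values in at least 19.8% of genes, and pairs across sets in at most 14.2%. The sets may thus have been prepared, sequenced or processed apart, although the labels name no batch. A difference between the animals of the sets, such as litter, was not tested and stays open.

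Q215X/+ differed from WT in 9 lists at the preset correlation and 0 with an estimated one, with red blood cell genes at a median of 2.07 log2 units. Erythroid genes outside that list had a median of 0.00215 over 13 testable genes, within the 95th percentile of 0.0429 of random lists (the bound set in advance against blood), and of −0.0983 in the double against Q215X/+, below the 5th percentile of −0.071. The bound was wrong and neither value decides, because all 13 were expressed in WT nerves (lowest mean 1.67 FPKM), where a small share of blood would not show, while of 12 erythroid genes below the filter 7 were higher in both Q215X/+ libraries than in both WT libraries and 0 were lower, where chance gives 16.7% each way, so red blood cells may have remained. Across autosomal genes the difference had r = 0.149 with male minus female in HA-NRG1 type III/+ (set 0 minus set 1, less the set difference of a group outside the comparison), the double minus Q215X/+ −0.0982 and the double minus WT −0.0422, and without short RNA genes 0.176, −0.00477 and −0.0813. By list, male minus female had medians of 1.58, −0.119, −0.0362 and −0.288 for red blood cell, endothelial, cholesterol and skeletal muscle genes, beside 2.07, −0.22, −0.20 and 1.02 for Q215X/+ minus WT. Red blood cell genes had −0.93 in the double against WT, both female, and −1.41 with the transgene alone, which holds a male library. Sex alone would give no difference in the former and a rise in the latter, so it does not account for either value. Cholesterol genes had −0.29 in the double against WT, both female, and 0.02 with the transgene alone, which goes against sex for that list. Endothelial genes had −0.02 in the double against WT, both female, which does not go against sex. With the transgene alone they had 0.01, where sex alone would give a value below 0 through the male library of that group. The double tests the mutation only beside the transgene, so sex, read from 1 library each, and the mutation cannot be told apart.

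The transgene effect was alike on both backgrounds for the 128 genes called in both comparisons with the block (1 to 26 genes without any one library and 1 with a term for sex, where all 128 kept their directions, as genes chosen from the same libraries tend to). Both groups read as female in the double against WT. There 115 of the 128 were called in the same direction with the block, with a median change of 0.65 log2 units. These libraries also served to choose the genes, so that share does not test sex. Sex runs in opposite directions in the 2 comparisons: HA-NRG1 type III/+ holds a male that WT lacks, and the double lacks the males of Q215X/+. An effect of sex alone would not give a gene the same direction in both, which argues against sex as the reason for the shared direction. The fullest 20 Mb window held 5 of these genes, against a median of 6 and a 95th percentile of 8 for random draws. That argues against 1 such region carried along with the transgene as the source of most of them. A region that holds a few of them would not show in this test. In a fit of 4 against 4 libraries, 2 of the 35 splits called as many genes as the 291 of the transgene split, so chance could not be excluded there, and the other was the split of the sets with 3746, which points to that structure of the libraries. Among the 18 splits balanced over the sets, with the block, the transgene split called 1054 and the highest other 1, and 18 splits are too few for a share under 0.05.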

How the results depend on the processing

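The terms for sex, the removal of short RNA or sex-linked genes, the block without a single library and the counts over both backgrounds were chosen after the result was seen. Of 131 named gene results, 25 were calls, and none reversed under the alternatives run for single genes, which are those with counts in this paragraph. Calls ended for 1 with a pseudocount of 0.1, 13 without a filter, 4 with quantile normalization, 2 with median ratio rescaling, 12 with a term for sex and 8 with that term and the block, and for 2 of 19 at a mean of at least 5 FPKM. Calls were gained for 42 with the block, 11 with the block and the term for sex and 1 with that term alone. Robust eBayes kept all 131. Leaving out 1 library ended 138 of 200 calls (25 in each of 8 fits) and added 2, where the lone sample is assumed to vary like the other groups. The block changed no list call other than those given beside the results. Otop1 in the double against WT kept its side of the threshold under each of these. The fits of only the libraries compared, of the block without a library and without short RNA genes were read as counts, not for single genes.

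The comparisons are numbered here as Q215X/+ against WT (1), HA-NRG1 type III/+ against WT (2), the double against Q215X/+ (3), the double against WT (4) and the interaction (5). Leave-one-out counts in this order were 1 to 15, 1 to 10, 1 to 17, 4 to 17 and 3 to 11 genes, and for 1 to 4 they were 8 to 11, 4 to 9, 10 to 11 and 6 to 11 lists. Without a filter, where more genes were tested, limma called 2, 0 and 3 genes in 1 to 3, and in 2 the adjusted p of Cyp2j13 was 0.0503. At a mean of at least 5 FPKM it called 4 in 2. At an adjusted p under 0.1 it called 17, 19 and 42 in 2 to 4. With only the libraries compared, and so fewer samples, it called 7, 2 and 4 in 1, 2 and 4. The block gave 265, 216 and 299 in 2 to 4. The term for sex gave 8, 9 and 9 in 1, 3 and 5, and with the block it gave 9, 11, 11, 98 and 9 in 1 to 5, with 5 lists in 1 and 6 in 3. Without short RNA genes, which removed Mir135a-1, counts were 0, 14 and 0 in 1, 3 and 5. The block without any one library gave 1 to 20, 4 to 221, 5 to 73, 8 to 241 and 3 to 12 in 1 to 5, and 1 to 26 genes called in the same direction in both 2 and 3, against 128 with all libraries and 1 with the term for sex. An estimated correlation left 0 lists in each of the 4 comparisons, and fry called 0, 1, 2 and 1. The correlation of transgene effects was 0.599 without sex-linked and short RNA genes and 0.094 to 0.261 in leave-one-out fits, and that of mutation effects −0.105 to 0.122. The shift of genes called for the mutation was 0.0714 when chosen in 1 set and measured in the other and −7.99 to 0 in leave-one-out fits. Over both backgrounds, the 124 transgene calls became 890 with the block, 22 with the term for sex, 304 with both and 11 to 42 in leave-one-out fits. The 1 mutation call became 2, 3, 4 and 3 to 13 in the same order, and 0 without short RNA genes. Where neither the number of genes nor that of samples changed, the cause was not tested. Library depth is unknown, so genes near 0 FPKM such as Nrg1 carry an error that these fits do not show.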

Other observations

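The comparison of all 4 libraries with the transgene against all 4 without it, the genes named from it and the test of same-direction mutation effects were chosen after the result was seen. With the set as a block, limma with Benjamini-Hochberg adjustment called 428 rises and 462 falls for the transgene over both backgrounds (67 and 57 without the block, 304 calls in all with the block and a term for sex, and 11 to 42 without the block and any one library). Otop1 rose by 2.30 log2 units (SE 0.07, n = 4 and 4, adjusted p = 0.000154), and Scube1, a secreted protein with EGF-like repeats, rose by 0.99 (adjusted p = 0.000885). Hapln2, a link protein of nodes of Ranvier, rose by 0.90 (adjusted p = 0.00379), and Timp1, an inhibitor of metalloproteases, by 0.86. Aldh1a1, which makes retinoic acid, fell by 1.11 (adjusted p = 0.00287), Tubb4a, a tubulin gene, fell by 1.14 (adjusted p = 0.00134), the axonal motor gene Kif5a fell by 0.90 (adjusted p = 0.00425) and Stmn3 of the stathmin family fell by 1.06.

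By list, myelin genes split into 2 rises and 9 falls over both backgrounds, fatty acid and sphingolipid genes into 3 and 4, axonal genes into 1 and 5 and macrophage genes into 7 and 1, all with the block. Fibroblast genes gave 4 rises and 0 falls, and red blood cell genes 0 rises and 4 falls, both by limma with 2917 genes at an unadjusted p under 0.05. Mag and Mbp, which encode myelin proteins, had log2 differences of −0.08 (adjusted p = 0.429) and −0.09 (adjusted p = 0.644), beside falls of Cnp by 0.87 (adjusted p = 0.00119), Mal by 0.32 (adjusted p = 0.0207) and Fa2h by 0.35 (adjusted p = 0.013). Erbb3 fell by 0.33 (adjusted p = 0.0159), while Erbb4 rose by 0.56 (adjusted p = 0.0036).

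For the mutation over both backgrounds, the block gave 2 rises and 0 falls, Mir135a-1 and Otop1 (log2 0.89, adjusted p = 0.0498), with 848 genes at an unadjusted p under 0.05. Without the block the count was 1, and 3 to 13 without any one library. Several genes that rose with the transgene also had positive mutation values that did not pass: Lect1 1.04 (adjusted p = 0.0964), Cyp2j13 0.67, Ephb1 0.59 and Emid1 0.54 (adjusted p = 0.0876 for the last 3). Ly9 had −0.39 (adjusted p = 0.0876). A hypothesis from these values was that the mutation moves transgene-responsive genes in the same direction. Of 889 such genes 53.7% had the same sign, against a 95th percentile of 52.9% for random draws (1-sided permutation p = 0.0184). Of the 20 genes with the strongest transgene effect, 10 had the same sign. Without sex-linked and short RNA genes, Pearson r across genes was −0.109 and Spearman rho 0.0357. Autosomal genes that follow sex would lower this r, because sex runs in opposite directions in the transgene and mutation effects. Red blood cell genes also went in opposite directions, with medians of −2.325 for the transgene and 1.223 for the mutation. The negative r thus does not by itself go against the hypothesis. A rule that the correlation also be above 0 was added after the share was seen, and the question stays open.

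In a fit of 4 against 4 libraries the mutation split called 0 genes with limma, with 177 at an unadjusted p under 0.05, and the highest other was the split of the sets with 3746. All 35 splits call at least 0, so their number decides nothing about chance.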
